A study of Homo sapiens with 8 samples.

How the data were processed

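Total RNA of 8 samples was hybridised to 8 single-colour long non-coding RNA arrays, with 4 groups of 2 samples: DLD-1 and SW480 cells that received either the wild-type APC coding sequence or a control vector. Per the labels' protocols, RNA was extracted with Trizol, amplified with random primers and labelled with Cy3. The authors deposited the scanner output of each array as linear intensity values with spot flags. Per the file headers, the processed intensity is background-subtracted by Agilent Feature Extraction within each array and is not scaled between arrays. The submitters' processing notes give Agilent Feature Extraction version 10.7.3.1, while the file headers give 11.0.1.1. The authors also deposited a table of log2 values for 58944 probes, which served as an alternative. Its columns have medians from 6.542 to 6.543 and correlate with the log2 intensity of their own array at r of 0.996 or more, so the scale and the array order are known, and the centring step is not given in the sources used here. Titles of the samples end in "cell" or "RNA", with 1 of each in every group, and the meaning of these endings is not given in the sources used here. Samples titled "cell" are called replicate 1 and those titled "RNA" replicate 2. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

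Each array holds 61184 spots, of which 1439 are marked as control spots. These control spots and 60 negative control sequences with 10 spots each were left out of the tests. Spots flagged as non-uniform or as population outliers were removed, spots of a probe were averaged on the log2 scale, and 317 of 58965 probes were left out because a flag left them without a value on some array. No saturated spot was marked. The log2 processed intensity of each array was centred on its 75th percentile over the remaining probes, and 48252 probes well above background on at least 2 of the 8 arrays were tested. All levels below are on this centred log2 scale.

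Of the probes, 20 carry a RefSeq transcript identifier in the files, and all 20 matched a gene symbol in the RefSeq gene table. All other probes carry the array maker's identifier only and are given by that identifier. APC probes were therefore not analysed here, and the level of the transfected gene, which would check the labels, is not reported. The headers name build hg19 and the reference tables another assembly, so no coordinates are printed. The 20 named transcripts have 10 spots on each array, and the values of 2 of them are not reported here, although they are included in the counts.

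Group means were fitted for all probes with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 4 residual degrees of freedom), and 5 contrasts were tested two-sided with Benjamini-Hochberg adjustment at a threshold of 0.05: APC against control in each line, the mean of both lines, the difference between the lines, and SW480 control against DLD-1 control. Errors of differences are standard errors (SE) of this fit, with 95% confidence intervals where given. The rule for named genes, fixed before the data were examined, takes called named genes with the largest changes, and where fewer pass, those with the smallest p up to 5 each way as values without a call. At most 2 unnamed probes are given each way. Where a probe was not well above background on any array of a group, its change is a lower bound. For this bound, the mean of the brighter group was set against a mean that takes, per array, the higher of the probe's own value and the lowest value among probes well above background. Of 29 gene lists fixed before the data were examined, 3 have at least 2 named members, and these were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The other 26 lists, which include the Wnt target genes, were not analysed here.

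All 8 arrays share 1 scan time, and the position codes in the headers place them on a slide of 2 rows by 4 columns. DLD-1 control and SW480 APC arrays lie in slide row 1, and DLD-1 APC and SW480 control arrays in slide row 2, so transfection and slide row cannot be told apart within a line. Arrays titled "cell" lie in slide columns 1 and 2 and those titled "RNA" in columns 3 and 4. The mean of both lines is balanced over the slide rows, and the difference between the lines follows the slide row exactly. The comparison of the control groups follows the slide row too, and an average of each line over its APC and control groups is balanced over the rows. Positions within an array are given by 384 rows and 164 columns of spots: the left side is columns 1 to 82, and the right side is divided at row 192 into an upper and a lower part. Spots of multi-spot probes were also averaged within these parts, for probes with at least 10 spots and well above background on at least 2 arrays. Spike-in, negative, mouse, rat and other control sequences are grouped as sequences without a human target, although the rodent sequences can bind the human homologue.

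The fit was tested on simulated data drawn from the real probe means and residual spreads, with 200 changed probes among 48252 in each comparison. In the simulation of APC against control in SW480, 56.1% of probes changed by 4 on the log2 scale, 8.96% of those changed by 2 and 0 of those changed by 1 were called. In that of DLD-1 the shares were 47%, 2.99% and 0, in that of the mean of both lines 77.3%, 41.8% and 0, in that of the difference between lines 27.3%, 0 and 0, and in that of the control groups 53%, 1.49% and 0. Between 0 and 4 unchanged probes were called in each simulation. The simulated noise was independent between probes and held no effect of array position or slide row. These counts therefore do not measure false calls on the real arrays. The shares called hold for 200 changed probes only, because the adjustment is less strict where more probes change. Between the real control groups 6661 probes were called, with 0.954 (log2) as the smallest called change. The number of arrays limits the precision of every comparison.

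Alternatives were quantile normalization, centring on the median, other filters on dim probes, only the samples compared, the title ending as a replicate block, trend and robust variances, the deposited log2 table, other thresholds and leaving out each array. Background correction with normexp (offset 50) was planned on the mean signal, which is not among the columns used, and was run on the median signal. This, the alternatives by position on the array and the average of each line over both slide rows were chosen after seeing the data.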

Results

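The arrays measured long non-coding and messenger RNA in DLD-1 and SW480, established colorectal adenocarcinoma cell lines that carry truncating mutations in APC, a negative regulator of Wnt signalling. Cells received wild-type APC or a control vector, and the comparisons ask which transcripts change when APC is restored and whether the lines respond alike. Between 69.0% and 78.8% of probes were well above background on each array. The 75th percentile of the processed signal ran from 332 on SW480 control replicate 2 to 678 on SW480 APC replicate 1. Replicates correlated at r = 0.957 in DLD-1 APC, 0.938 in DLD-1 control and 0.968 in both SW480 groups across probes. The first principal component, with 58.3% of the variance, separated the cell lines. The second component ran from -103.1 on SW480 control replicate 2 to 120.2 on DLD-1 control replicate 1.

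In DLD-1, none of the 20 named transcripts passed the test for a difference between APC and control. PGK1, a glycolytic enzyme, was at 2.29 ± 0.35 with APC and 1.91 ± 0.11 with control (centred log2 level, SD, n = 2 arrays each), a difference of 0.38 ± 0.38 (SE). ODC1, the rate-limiting enzyme of polyamine synthesis and a known MYC target, differed by -0.31 ± 0.32. The differences of the arginine methyltransferase PRMT1 (-0.36 ± 0.27), the histone H3.3 gene H3-3A (-0.27 ± 0.28) and the ribosomal protein gene RPL10 (0.31 ± 0.29) were of similar size. The RPL10 probe was dim, at -0.57 with APC and -0.88 with control, against 8.46 and 8.66 for the ribosomal protein gene RPLP1. ACTG1 and MTX1 differed by 0.04 ± 0.29 and 0.01 ± 0.28. GRM4, a glutamate receptor gene near background, differed by -0.87 ± 0.45, and its difference was -0.30 at left spots and -1.53 at lower right spots of the arrays. In limma all 20 had an adjusted p of 1 over all probes and 0.97 adjusted over the 20 alone, and none had an unadjusted p under 0.05.

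Among the unnamed probes, 11 of 48252 were called in DLD-1, of which 4 rose and 7 fell (limma, adjusted p under 0.05), and 2601 had an unadjusted p under 0.05 where chance alone gives 2413. ASHGA5P004644 rose by 6.96 ± 0.40 on the log2 scale (limma adjusted p = 0.038, well above background on 1 of 2 control arrays), and ASHGA5P038539 was at least 4.34-fold higher with APC (limma adjusted p = 0.04). ASHGA5P000649 was at least 87.2-fold lower and ASHGA5P005396 at least 33.4-fold lower with APC (limma adjusted p = 0.04 for both). All 11 probes had the opposite sign in SW480, and 9 of them lie on the right side of the arrays, which holds 49.3% of tested probes. No probe was called when any DLD-1 array was left out or on the left side alone, and 1 was called when any SW480 array was left out. With normexp on the median signal 2 rose and 15 fell, and with the deposited log2 values 4 rose and 3 fell. With the title ending as a replicate block 0 probes were called.

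In SW480, the named transcripts with the smallest p were again not past the threshold. ODC1 was at 6.01 ± 0.35 with APC and 5.46 ± 0.03 with control (SD, n = 2), a difference of 0.55 ± 0.32 (SE), or 1.47-fold, with a 95% interval from -0.21 to 1.32. PGK1 differed by 0.40 ± 0.38, close to its value in DLD-1. Its separate 3' control probe did not share this rise, at -0.04 in SW480 and 0.16 in DLD-1. The 5' control probe differed by 0.63 and 0.33. H3-3A (-0.52 ± 0.28), the cytoskeletal actin gene ACTG1 (-0.50 ± 0.29) and the ribosomal protein genes RPLP1 (-0.42 ± 0.27) and RPS18 (-0.40 ± 0.26) lay below 0, and GRM4 was at 0.14 ± 0.45. Of the 20 named transcripts 17 lay below 0 with a median of -0.25, but the median was 0.067 after quantile normalization, with 7 below 0. Their lowest adjusted p in limma was 0.57 over all probes and 0.54 adjusted over the 20 alone, and none had an unadjusted p under 0.05.

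**Figure D1:**
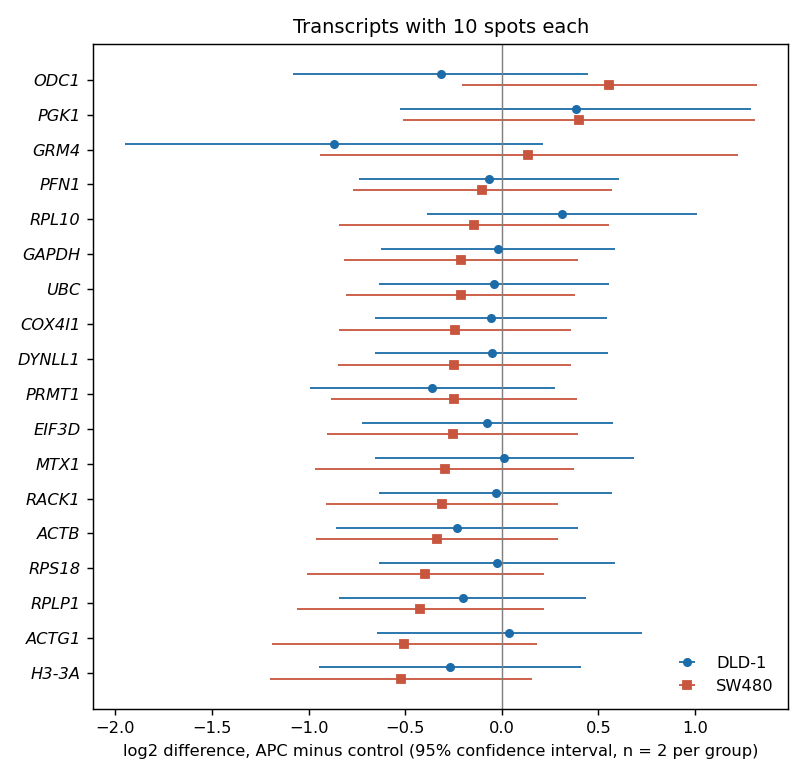
Differences between APC and control (log2, x axis) of 18 named transcripts, with points for DLD-1 (circles) and SW480 (squares) and bars for 95% confidence intervals of the limma fit (n = 2 arrays per group). Every interval includes 0, and ODC1 lies at -0.31 in DLD-1 and 0.55 in SW480.

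Unnamed probes gave more calls in SW480 than in DLD-1: 164 of 48252 were called, of which 134 rose and 30 fell (limma, adjusted p under 0.05), and 5008 had an unadjusted p under 0.05. ASHGA5P005396 was at least 19.8-fold higher with APC and ASHGA5P005228 at least 29.2-fold higher, while ASHGA5P048083 was at least 22.6-fold lower and ASHGA5P026714 at least 10.6-fold lower (limma adjusted p from 0.016 to 0.019). Of the 164 probes 158 lie on the right side of the arrays, and 152 had the opposite sign in DLD-1. The rises lay mostly in the lower right, with 128 of 134, and the falls in the upper right, with 27 of 30. Tested alone, the left side gave 0 called probes and the right side 451. No probe was called without SW480 APC replicate 1 or 2 or SW480 control replicate 2, 7 were called without SW480 control replicate 1, and 526 without either DLD-1 control array. With normexp on the median signal 6 rose and 4 fell. The title ending as a replicate block gave 80 calls, trend and robust variances 60, and probes well above background on all 8 arrays 0. Only the SW480 samples gave 718.

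**Figure D2:**
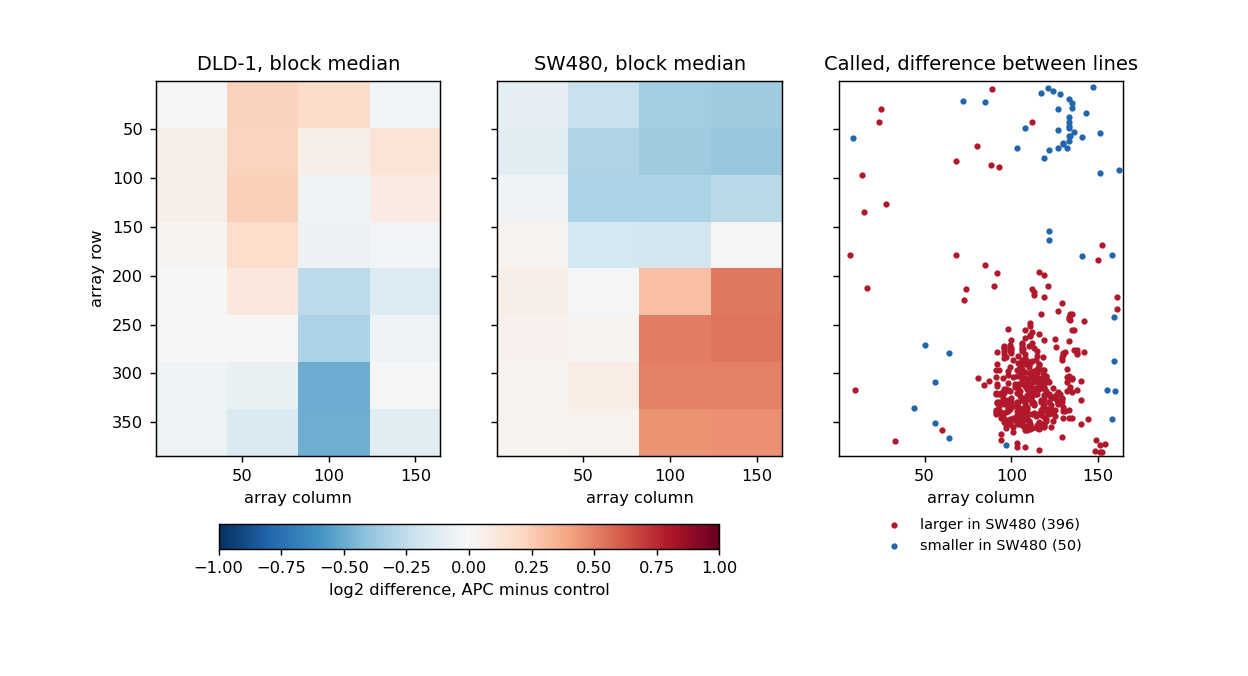
Position on the array (columns on the x axis, rows on the y axis) of the APC response: median log2 difference per block of spots in DLD-1 (left panel) and SW480 (middle panel), and the 446 probes called for the difference between the lines (right panel). The 396 probes with a higher signed difference in SW480 than in DLD-1 (labelled larger in SW480) gather in the lower right. There DLD-1 medians lie at or below 0 and SW480 medians above 0.

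Averaged over both lines, no named transcript and no other probe changed past the threshold. PGK1 differed by 0.39 ± 0.27 (SE), ODC1 by 0.12 ± 0.23 and RPL10 by 0.08 ± 0.21. The separate 3' and 5' control probes of PGK1 differed by 0.06 and 0.48. H3-3A differed by -0.40 ± 0.20, RPLP1 by -0.31 ± 0.19, PRMT1 by -0.30 ± 0.19 and ACTB by -0.28 ± 0.19, and each 95% interval included 0. Limma called 0 of 48252 probes, with 2017 at an unadjusted p under 0.05 against 2413 given by chance, and the adjusted p of the named transcripts was 0.93 or more over all probes and 0.64 or more over the 20 alone. The smallest adjusted p of any probe was 0.76.

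The lines were compared directly through the difference of their responses. ODC1 differed most by p among the named transcripts, by 0.87 ± 0.45 (SE), followed by GRM4 at 1.0 ± 0.64. PRMT1 (0.11 ± 0.38) and PGK1 (0.01 ± 0.54) lay near 0. ACTG1 differed by -0.54 ± 0.41, RPL10 by -0.45 ± 0.41, RPS18 by -0.37 ± 0.36, MTX1 by -0.31 ± 0.40 and RACK1 by -0.28 ± 0.36. None of the 20 passed in limma, with a lowest adjusted p of 0.62 over all probes and 0.94 over the 20 alone.

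Among all probes 446 differed between the lines in their response (limma, adjusted p under 0.05). The signed response, APC minus control, was higher in SW480 than in DLD-1 for 396 and lower for 50, whichever line changed more in size. Of the 446 probes 443 had opposite signs in the lines, 422 lie on the right side of the arrays, and 373 of the 396 lie in the lower right. Across all tested probes the responses of the lines correlated at r = -0.395, at -0.287 on the left side and at -0.433 on the right side. The left-side value also varied with position, from -0.524 to 0.0343 over its blocks of spots. In the lower part of the outer left columns it was -0.0365 (6100 probes). Probes are not independent replicates. No probe was called in the same direction in both lines, where independent lists would share 0.011 rises and 0.0044 falls, and 9 were called in opposite directions (3 rose and 6 fell in DLD-1). The difference follows the slide row exactly. On the left side alone 3 probes were called and on the right side 771. Leaving out SW480 APC replicate 1 or 2 gave 38 or 29 calls, SW480 control replicate 1 or 2 gave 112 or 67, DLD-1 APC replicate 2 gave 218 and DLD-1 control replicate 2 gave 918, and the correlation was -0.102 without DLD-1 APC replicate 2 and -0.0292 without DLD-1 control replicate 1.

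The control groups of the lines differed widely. PGK1 was lower in SW480, at 0.25 ± 0.42 against 1.91 ± 0.11 in DLD-1 (SD, n = 2), a difference of -1.66 ± 0.38 (SE, limma adjusted p = 0.033 over all probes and 0.074 over the 20 alone). The translation initiation factor EIF3D (0.84 ± 0.27), PRMT1 (0.75 ± 0.27), ACTG1 (0.69 ± 0.29) and the ribosomal scaffold RACK1 (0.57 ± 0.25) lay above 0, without a call. MTX1, a mitochondrial import gene, differed by -0.66 ± 0.28, RPL10 by -0.38 ± 0.29 and the cytochrome oxidase gene COX4I1 by -0.13 ± 0.25, also without a call. The separate 3' and 5' control probes of PGK1 differed by -0.81 and -1.24 in the same direction. The PGK1 call was lost when any of the 4 control arrays was left out, at differences from -1.96 to -1.36 with limma adjusted p from 0.07 to 0.17.

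Of all probes 6661 differed between the control groups, with 3266 higher and 3395 lower in SW480 (limma, adjusted p under 0.05). ASHGA5P036267 was at least 1210-fold and ASHGA5P017565 at least 539-fold higher in SW480, and ASHGA5P004447 was at least 1400-fold and ASHGA5P037365 at least 1180-fold lower (limma adjusted p from 7.6e-05 to 0.00013). All 4 lie on the left side of the arrays. Well above background on every DLD-1 array and on no SW480 array were 460 probes, and 528 showed the reverse. Calls were made for 11.8% of probes on the left side, 12.1% in the upper right and 19.7% in the lower right, with 1663 higher and 1224 lower in SW480 on the left side and 774 higher and 1566 lower in the lower right. The control groups also lie in different slide rows, so line and slide row cannot be told apart in this comparison. With each line averaged over its APC and control arrays, and so over both slide rows (chosen after seeing the data), 6056 probes were higher and 4296 lower in SW480 (limma, adjusted p under 0.05), with 1611 higher and 1097 lower in the lower right, and PGK1 differed by -1.65 ± 0.27 (SE). There were 4021 calls without DLD-1 control replicate 1, 3347 without SW480 control replicate 1 and 3517 without SW480 control replicate 2.

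Of the fixed gene lists, the cytoskeleton and migration list had 3 named members (ACTB, ACTG1 and PFN1), the ribosomal protein list 2 (RPLP1 and RPS18), and the hypoxia and glycolysis list 2 (GAPDH and PGK1). In SW480 all 3 cytoskeletal members lay below 0, with a mean of -0.31 (ACTG1 -0.50, ACTB -0.34, PFN1 -0.10). The mean of the ribosomal members was -0.41. Both lists had an adjusted p of 0.18 in limma's camera, and an adjusted p of 0.42 with an estimated correlation. In SW480 the sign of the median over all 20 named transcripts depended on the scaling. It was -0.25 as reported, 0.067 after quantile normalization and -0.19 when centred on the array median. These medians are not of the list members alone. In DLD-1 the list means were -0.09, -0.11 and 0.18 for the cytoskeletal, ribosomal and glycolytic members (limma's camera, adjusted p = 0.68 for each). The glycolytic pair had a mean of 0.09 in SW480, with PGK1 at 0.40 and GAPDH at -0.21. Its test in limma's camera, which sets list members against the other probes, was directed downward (adjusted p = 0.97). For the mean of both lines the lowest adjusted p was 0.14, for the difference between lines 0.54, and between the control groups 0.49, so limma's camera called no list in any comparison. Between the control groups the cytoskeletal mean was 0.38, the ribosomal 0.23 and the glycolytic -0.77.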

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

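The tests on the position of the calls were chosen after the results were seen, and the count of splits was planned. The response to APC differed between the lines for 446 probes, by limma's test of the difference itself, and 94.6% of these probes lie on the right side of the arrays (exact 95% interval from 92.1% to 96.5%), against 49.3% of tested probes. Opposite transcriptional responses of the lines, or exchanged APC and control labels in one line, would not depend on where a probe lies: tested alone, the left side gave 3 called probes and the right side 771, which argues against either as the whole cause. Removing the local median of the array position still left 182 called probes. The correlation between the lines was then -0.322, against -0.395 before. Uneven background light also seems an unlikely cause of the called rises. The 5th percentile of raw signal shifted by 5 in the lower right and by 3 on the left side in SW480. The excess of 2 is only 2.74% of the median raw rise of the 128 called probes in the lower right. A candidate explanation is non-specific hybridisation that depends on the position on the array: sequences without a human target, spotted in several places, differed between SW480 APC and control by a median of 1.38 more (log2) in the lower right than on the left side, and 29 of 33 differed upward. For 23 human transcript probes, the same median was 0.008, with GRM4, near background, highest at 0.78. Most named human transcripts have signals far above the median raw rise of the called probes (73.1), which would hardly show in them. The human median therefore cannot tell non-specific hybridisation from another effect on dim spots. What gave rise to the position effect, and any smaller response beneath it, stays open.

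Signal in control sequences, which the comparisons do not use, was above the level of the control vector arrays at lower right spots in SW480, for the probes below, and not at their other SW480 spots. The ERCC-00097 spike-in probe differed between SW480 APC and control by 2.60 (log2) at lower right spots, by -1.67 at upper right spots and by -0.84 at left spots. The negative control sequence Negative059 differed by 3.44 at lower right spots, by -0.73 at upper right spots and by -0.07 at left spots. At the same lower right spots the DLD-1 differences were -0.83 and -0.59.

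The 5' probe relative to the 3' probe of human GAPDH was higher with APC by 0.33 (log2, mean of both lines), and that of PGK1 by 0.42. In SW480 the differences were 0.55 for GAPDH and 0.67 for PGK1, and in DLD-1 0.12 and 0.17. The GAPDH value was -1.23 ± 0.03 with APC and -1.78 ± 0.25 with control in SW480 (SD, n = 2). An exact two-sided permutation test within lines gave p = 0.111 for both genes, where the 36 arrangements allow no p under 0.056.

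For the mean of both lines, the 18 splits of the samples within lines are too few for a share under 0.05. The real split called 0 probes, so no split can call fewer, and the highest other split called 1151. That split sets the SW480 transfection groups together with the DLD-1 title endings. It also sets the arrays with the highest 75th percentile of processed signal (542 to 678) against the rest (332 to 491). Its sides have opposite signs on the second principal component. Signal strength thus also separates the SW480 APC arrays from the SW480 control arrays, and its part in the calls was not tested. The split along the slide rows called 446 and is the difference between the lines given above.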

How the results depend on the processing

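Background correction on the median signal, the parts of the array, the local median and the fit of the 20 named transcripts alone were chosen after seeing the data; the cause of the changes was not tested unless stated. Counts below are called probes in the order DLD-1, SW480 and difference between lines, against 11, 164 and 446. Quantile normalization gave 21 in DLD-1. Without a filter on dim probes 1 and 106 were called in DLD-1 and SW480, and with probes well above background on all 8 arrays 0, 0 and 115. Trend and robust variances gave 60 in SW480 and 287 for the difference, and the deposited log2 values 7 in DLD-1. With normexp on the median signal the counts were 17, 10 and 119, and with quantile normalization after it 9 in SW480 and 215 for the difference. Removing the local median left 5, 77 and 182, of which 4, 70 and 177 were also called before. The left side alone gave 0, 0 and 3, and the right side 64, 451 and 771, with fewer probes tested. Normexp moved the median of all probes to -0.17 in SW480, -0.12 for the mean of both lines and 0.14 between control groups. Only the samples compared gave 0 in DLD-1, 718 in SW480 and 4269 between control groups. An unadjusted p under 0.05 with a 2-fold change gave 1921, 4102 and 4736, 688 for the mean of both lines and 10647 between control groups. Between control groups, against 6661, the left side gave 2781, the right side 3884 and the average of each line over both slide rows 10352. The mean of both lines kept 0 called probes in limma in every other setting (2017 at an unadjusted p under 0.05 in the reported fit).

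The title ending was not taken as a pairing: deviations correlated between groups at r from 0.0986 to 0.487, over 0.1 in 5 of 6 pairs of groups and not in every one. With the ending as a replicate block, 0 probes were called in DLD-1 and 80 in SW480, and no other call changed by over 1.5 times. Leaving out each array gave from 0 to 1 in DLD-1, 0 to 526 in SW480, 29 to 918 for the difference, 3347 to 6653 between control groups and 0 throughout for the mean. The correlation between lines, -0.395, ran from -0.527 to -0.0292. A lone array left in a group is assumed to vary like the others. The correlation was -0.207 with normexp and -0.272 with normexp and quantile normalization. List tests gave 0 calls in every setting run.

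The 45 pairs of named transcript and comparison picked by the rule for named genes were given under 807 alternatives. These do not cover all 20 transcripts in each comparison. Over all 20, quantile normalization took the number below 0 from 16 to 8 in DLD-1 and from 17 to 7 in SW480. For the mean of both lines it went from 17 to 6. Of the 807 alternatives 768 kept sign and side of the threshold, 24 changed sign without a call in either fit, 11 gained a call and 4 lost it. The gains were between control groups, and included EIF3D, PRMT1, ACTG1 and RACK1 with trend and robust variances, these and MTX1 in the fit of the 20 alone, and MTX1 with normexp and quantile normalization. The planned normexp on the mean signal, the slide or scan date as a block (1 scan time) and the mean of probes per gene (1 probe each) were not run. Signal over background limits GRM4, which was well above background on 1 of 2 DLD-1 APC arrays.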

Other observations

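Most human transcripts with 10 spots were measured precisely within each array, with a median SD between spots of 0.0532 (log2), so the spread between arrays sets their error. In a fit of the 20 named transcripts alone, chosen after seeing the data, the SE of a within-line difference had a median of 0.161, against 0.276 in the fit of all probes. Between the control groups 8 of the 20 then passed (limma, adjusted over the 20 alone). Among them EIF3D, PRMT1, ODC1, ACTG1 and RACK1 were higher in SW480 and PGK1 and MTX1 lower. None of the 20 passed for APC against control in either line or for the difference between lines. ODC1 had the smallest p of the 20 for that difference, with 0.43 as its limma adjusted p in this fit.

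The 5' probes of the human control transcripts were higher with APC in SW480, GAPDH by 0.36 and PGK1 by 0.63 (log2), while the 3' probes differed by -0.18 and -0.04. These values were alike at left, upper right and lower right spots, from 0.34 to 0.41 for the GAPDH 5' probe and from 0.62 to 0.65 for the PGK1 5' probe.

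The title ending, as a term in the limma fit, called 0 probes, with 8794 of 48252 at an unadjusted p under 0.05 against 2413 given by chance. Each ending lies in its own slide columns, so title ending and slide column cannot be told apart. Well above background on all 4 arrays titled "RNA" and none titled "cell" were 68 probes, and 12 showed the reverse. All 4 APC arrays and no control array detected 9 probes, of which 1 lies on the right side of the arrays, and 0 probes showed the reverse. Along the slide rows these counts were 179 and 13, and 171 of the 179 lie on the right side of the arrays.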
